A study of Homo sapiens with 6 samples.

How the data were processed

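Gene expression was measured in 3 established human non-small cell lung cancer lines, H441 and H1437 (adenocarcinoma) and H292 (mucoepidermoid carcinoma). Per the labels' protocols, each line was transduced with a retrovirus made in 293T cells that carried either the empty pLHCX vector or the same vector with a wild-type Snail cDNA, and was selected and grown with hygromycin B at 350 µg/mL. Snail, encoded by SNAI1, is a zinc finger repressor of E-cadherin (CDH1) transcription and an inducer of the epithelial-mesenchymal transition (EMT). Total RNA from cultures of similar confluence was labelled with biotin and hybridised to 1 Affymetrix array per line and construct, which gives 6 arrays, 3 of them labelled vector and 3 labelled Snail. The design text states that Snail and E-cadherin protein were compared by Western blot, and those blots were not analysed here.

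The deposited values are intensities on a linear scale, 1 per probe set and array, for 54675 probe sets. The algorithm the authors used for background correction, summarisation and scaling is not given in the sources used here. The values had a floor, since between 955 and 1048 probe sets per array were listed at exactly 1. The array medians on the log2 scale lay within 0.06 of each other, so the deposited intensities were used without further scaling. Probe sets were named from the platform's annotation table, whose symbols were looked up by Entrez identifier in a RefSeq gene table of the GRCh38.p14 assembly, used for names only. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none in that table. Those with several or none were left out, as were 62 control probe sets. No symbol needed updating, and 54 probe sets with 1 symbol were not found by identifier and kept the symbol of the annotation table.

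Intensities were turned into log2(intensity + 16), so every log2 ratio is on that scale and understates the change of dim probe sets. Each gene was represented by the probe set with the highest mean over the 6 arrays, which left 19775 genes. Genes were tested if this probe set lay at or above the median of its array in at least 3 of the 6 arrays, which left 12683 genes. Within a line, a gene was counted as measured if the brighter of the 2 arrays lay at or above its own median. Among genes named below and changed over 2-fold within a line, 126 further measured probe sets could be compared with the one used. Of these, 122 had the same direction, 30 of them by under 2-fold and 43 at over 1.5 times less than the log2 ratio used, and 4 the opposite one, none of these by over 2-fold.

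Snail-labelled and vector arrays were compared with limma 3.58.1 in R 4.3.3, with the cell line as a block, moderated 2-sided tests and Benjamini-Hochberg adjustment over all genes tested at 0.05. The block left 2 residual degrees of freedom before moderation. The pairs come from the cell line named in the labels, and the arrays of a line correlated with each other at 0.949 to 0.981 over all probe sets, controls included, against 0.890 to 0.922 for arrays of different lines. The fit without the block was run as an alternative. With 1 array per line and construct, p-values of single genes measure the spread of the ratio between 3 lines, and no value within a line has a replicate check. Differences between lines were tested with the F test of the cell line terms in the same model. The comparison by histology set the ratio in H292 against the mean ratio of H441 and H1437, with H292 assumed to vary like the others and 1 residual degree of freedom. SNAI1 and CDH1 were also tested with a 2-sided exact sign-flip permutation test over the 3 lines, whose smallest possible p is 0.25.

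Before the data were examined, 25 gene lists were fixed, covering junctions, keratins, mesenchymal genes, EMT transcription factors, chemokines that bind the receptor CXCR2, cytokines, matrix, integrins, transforming growth factor beta (TGF-beta) response, stem cell associated genes, proliferation, stress, metabolism, interferon response, lung lineage, growth factor receptors, ribosomal proteins, and markers of leukocytes, fibroblasts, endothelium and 293-derived cells. Of 595 listed symbols, 543 were named on the array. Lists with at least 5 tested members, 23 in all, were tested with limma's camera at a preset correlation between genes of 0.01, with the correlation estimated from the data and with the rotation test fry as alternatives. At the preset correlation, camera's p-values rest on the number of members and the spread over genes. A small one does not show that the 3 lines agree. Within each line, the median log2 ratio of a list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called outside the random range where its median lies below the 2.5th or above the 97.5th percentile, as a description of these arrays only.

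The genes named in the text follow a rule fixed together with the lists. It takes SNAI1 and CDH1; the 10 largest rises and falls past the threshold over the 3 lines, filled up with tested genes that moved the same way in all 3 lines, ranked by the smallest of their 3 ratios; up to 4 members per list with the largest mean change and any member of the CXCR2 ligand and EMT transcription factor lists; the 5 largest rises and falls within each line; and the 3 genes most specific to each line. Other genes are named with a statement that they were chosen after their values were seen.

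The steps were tested on simulated data with the spread and the 12683 genes of the real arrays. For Snail-labelled against vector arrays, with 50 genes changed per size, limma recovered 2% of genes changed by 1 on the log2 scale, 82% at 2, 92% at 3 and 98% at 4, with 9 false calls. The F test between lines recovered 182 of 200 genes changed by 3, with 6 false calls. The test of the histology difference recovered 0 of 200 genes changed by 3, so a count of 0 from it says nothing about the lines. For the lists, the 1 list shifted by 1 was found and 0 of 20 others were called. The simulated genes varied independently of each other and the lists were random genes. This count therefore cannot show how often camera with a preset correlation falsely calls a list of genes that vary together. The simulation lets a change be equal in every line, which the real ratios were not. It also gave every line the same spread. The real ratios over measured genes had an SD of 0.40 in H441, 0.51 in H292 and 0.82 in H1437. Genes of all sizes were changed together, and many true changes ease the adjustment for each. The recovered shares therefore do not make a count of 0 in the real data evidence against shared changes of these sizes.

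Alternatives were quantile normalization, centring of each array on its median, pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, the mean of all probe sets of a gene, every probe set on its own, no block, limma's trended and robust moderation, array weights, an unmoderated paired fit, thresholds of 1.5-fold and 3-fold, an adjusted p threshold of 0.1, and leaving out each cell line in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of all values. The ratio of 3' to 5' signal of the GAPDH control probe sets lay between 0.944 and 1.00 and that of ACTB between 1.03 and 1.32.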

Results

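Transcript levels were read from 6 arrays, 1 labelled vector and 1 labelled Snail for each of the lung cancer lines H441, H292 and H1437. The comparisons ask which transcripts differ between cells given a Snail retrovirus and cells given the empty vector, whether the 3 lines share these differences, and whether they differ by histology. The median intensity per array lay between 32.4 and 34.4. No array was replicated, so values within a line carry no error, and the SD given for a mean is the spread of the ratio over n = 3 lines. All ratios are of the Snail-labelled over the vector array on the log2(intensity + 16) scale.

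SNAI1, the gene carried by the virus, was clearly brighter in the Snail-labelled array of H1437 alone. Its probe set 219480_at read 43.8 in the vector array and 293.2 in the Snail-labelled array of H1437, a log2 ratio of 2.37. In H292 it read 24.0 and 29.0, both below the median of their array, so that it was not measured there, a ratio of 0.17, and in H441 it read 56.3 and 41.2, a ratio of -0.34. The mean ratio was 0.73 ± 1.44 (SD, n = 3 lines) with an exact sign-flip permutation p of 0.75, and without H1437 it was -0.08. Where this probe set lies relative to the transduced cDNA is not given in the sources used here, and a probe set outside the cDNA would not read the transgene. Because the level does not follow the label in H441 and does not check it in H292, the arrays are called Snail-labelled throughout.

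CDH1, which encodes the adherens junction protein E-cadherin, was lower in the Snail-labelled array of every line at its brighter probe set, 201131_s_at. The intensity was 2299 in the vector array and 375.6 in the Snail-labelled array of H1437, a ratio of -2.56. The same probe set gave 2375 and 2071 in H441, a ratio of -0.20, and 2461 and 2038 in H292, a ratio of -0.27. These ratios of H441 and H292 lay within the spread over all measured genes of the line, 0.32 and 0.41. That spread is the median absolute deviation scaled to an SD. The mean was -1.01 ± 1.35 (SD, n = 3 lines) with an exact sign-flip permutation p of 0.25, the smallest possible with 3 lines, and without H1437 it was -0.23. The dimmer probe set 201130_s_at gave 0.07 in H441, -0.79 in H292 and -2.46 in H1437.

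**Figure D1:**
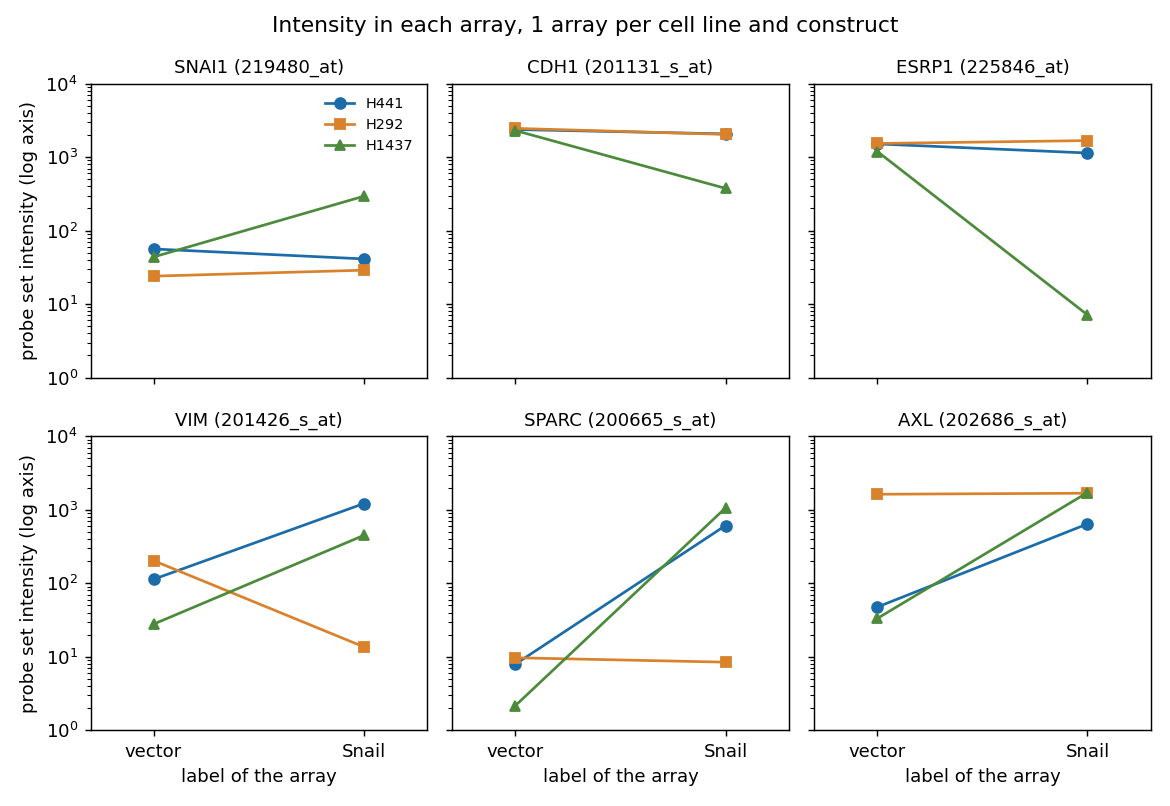
Intensity of 1 probe set each for 6 genes (vertical axis, log scale) in the arrays labelled vector and Snail (horizontal axis), with 1 point per array and a line joining the arrays of a cell line. SNAI1 reads 293.2 in the Snail-labelled H1437 array against 41.2 in H441 and 29.0 in H292, and VIM, chosen after its values were seen, is higher in H441 and H1437 and lower in H292.

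Over the 3 lines, the genes over 2-fold higher in every Snail-labelled array were TNFAIP3, TUBA1A, SAMD9 and SOX9. TNFAIP3, a ubiquitin-editing inhibitor of NF-kB signalling, had ratios of 1.56 in H441, 2.67 in H292 and 2.05 in H1437, a mean of 2.09 ± 0.56 (SD, n = 3 lines). SOX9, a transcription factor of developing airway epithelium, had a mean of 1.35 ± 0.26, and the alpha-tubulin gene TUBA1A a mean of 2.48 ± 1.93, with 4.70 in H1437. SAMD9, an interferon-inducible gene, averaged 1.59 ± 0.40. At a further measured probe set SOX9 had 0.82 in H441 and SAMD9 0.92 in H292, both under 2-fold. The other genes taken by the rule as higher were THBS1, which encodes the matrix protein thrombospondin 1 (1.26 ± 0.31, with 5 further probe sets between 1.68 and 2.20 in H441 and 4 between 0.65 and 2.37 in H1437), IFI6 (2.20 ± 1.26), ADAM19 (1.19 ± 0.51), TMEM45A (1.71 ± 0.73), EMP3 (2.57 ± 1.78) and LCAT (1.20 ± 0.35). In H441, LCAT read 1 and 25.96, both below the median of their array, so that it was not measured there.

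Over 2-fold lower in every Snail-labelled array were AGR2, a disulfide isomerase needed for mucin folding, and the tetraspanin gene TSPAN1. AGR2 had ratios of -1.52 in H441, -1.22 in H292 and -5.49 in H1437, a mean of -2.74 ± 2.38 (SD, n = 3 lines), and TSPAN1 a mean of -1.30 ± 0.21. The keratin gene KRT15 averaged -1.15 ± 0.31, GCNT3, a mucin-type glycosyltransferase, -1.06 ± 0.14, and SCEL, which encodes the cornified envelope protein sciellin, -1.36 ± 0.59. SMIM22, REEP6, PPFIBP2, CAPN8 and RNF43 were the remaining genes of this group, with means between -1.92 for SMIM22 and -0.94 for CAPN8. In H292, CAPN8 read 25.53 and 6.41, both below the median of their array, so that it was not measured there. None of these 20 genes passed the threshold.

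With the line as a block, limma called 0 of 12683 genes (smallest adjusted p 0.9996), and 501 genes had an unadjusted p under 0.05, against 634 by chance. Without the block it also called 0, with 56 at an unadjusted p under 0.05. Without H1437, the line with the largest differences, 4 genes passed, which were TNFAIP3, LCN2, BST2 and CHRM3, the last of them named after its values were seen. That fit keeps H441 and H292 alone and has fewer residual degrees of freedom, so its calls lean on the moderation. LCN2 was lower in both lines but had a ratio of 1.10 in H1437. BST2 was higher in both and had 0.15 in H1437. The cell line took 79.1% of the sum of squares over tested genes, the construct 7.62% and the rest 13.3%. The rest has 2 degrees of freedom. A construct without any effect would take a share near that of the rest per degree of freedom, and the observed share was close to it.

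**Figure D2:**
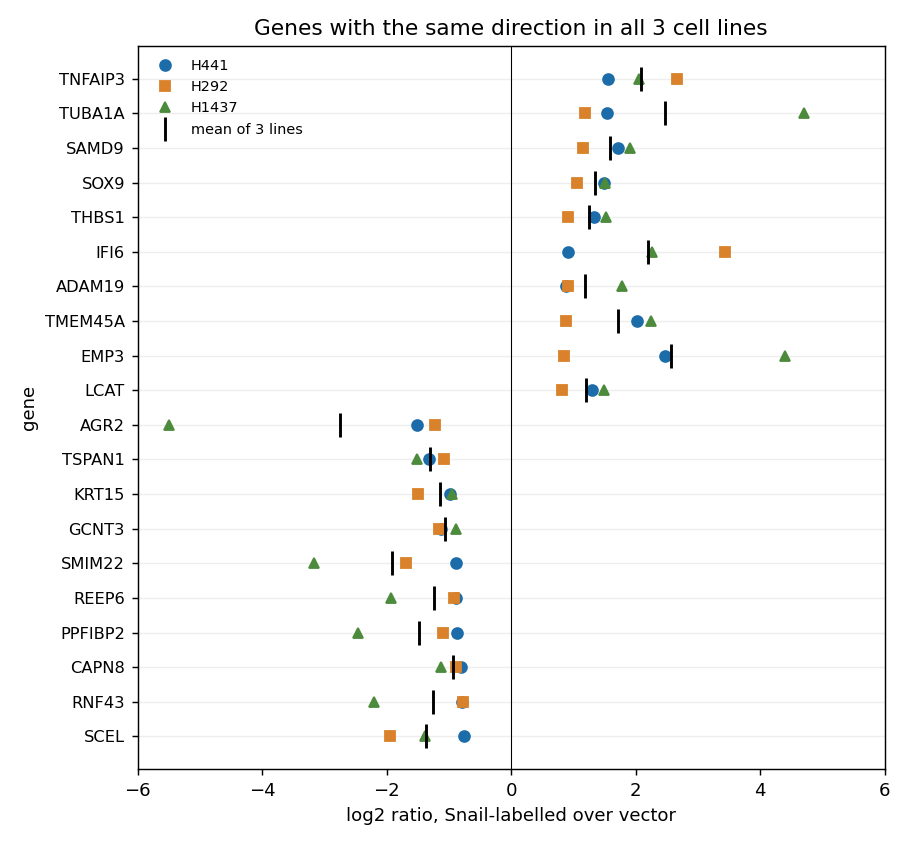
Log2 ratio of the Snail-labelled over the vector array (horizontal axis) in each of the 3 cell lines for the 20 genes named over the 3 lines (vertical axis), with a point per line and a bar at the mean. TNFAIP3 lies between 1.56 and 2.67, and AGR2 reaches -5.49 in H1437. LCAT in H441 and CAPN8 in H292 lay below the array median.

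Genes of epithelial junctions and their regulators were lower in the Snail-labelled arrays as a group, with the largest ratios in H1437. In H1437, 28 of 37 measured members were over 2-fold lower and 0 higher, with a list median of -2.15, below all 10000 random lists. ESRP1, an epithelial splicing regulator, went from 1192 to 7.13 there, a ratio of -5.71, against -0.40 in H441 and 0.13 in H292. Cingulin (CGN) had a ratio of -4.97 in H1437, the serine protease gene ST14 -4.55 and the epithelial transcription factor gene ELF3 -3.32. In H441 the list median was -0.39, again below all random lists, with 2 of 36 members over 2-fold lower, ELF3 at -1.20 (-0.74 and -1.16 at its further probe sets) and the protease gene PRSS8, named after its values were seen, at -1.38. In H292 the median was -0.05, at the 45.1st percentile, and 0 of 36 members moved by over 2-fold.

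Desmosome and keratin genes followed, with medians of -0.20 in H441, -0.21 in H292 and -0.96 in H1437, all outside the random range. Keratin 19 (KRT19) had ratios of -0.58, -0.81 and -3.37 in H441, H292 and H1437, the desmosomal plaque gene PKP2 -0.20, -0.64 and -3.29 (-1.0 in H1437 at its other measured probe set), and periplakin (PPL) -0.04, -1.37 and -2.13. By limma's camera with a preset correlation, both lists were lower over the 3 lines, with adjusted p of 3.43e-14 for junctions (mean of 37 tested members -0.85) and 2.59e-06 for desmosomes and keratins (mean of 17 members -0.53). With an estimated correlation, camera gave an adjusted p = 0.503 for both, and without H1437 the means with the preset correlation were -0.24 and -0.21. Of single members, 0 junction genes and 1 desmosome or keratin gene, KRT15, passed when adjusted over the list alone, and 0 over all genes tested.

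Mesenchymal genes were higher as a group in H441 and H1437. In H441, 11 of 22 measured members were over 2-fold higher and 0 lower, with a list median of 0.90, and in H1437 20 of 24 were higher and 0 lower, with a median of 2.38, both above all random lists. AXL, a receptor tyrosine kinase, had ratios of 3.37 in H441 and 5.14 in H1437 (1.35 and 3.15 at its other measured probe set), and myosin light chain kinase (MYLK) 2.06 and 3.38. Caldesmon (CALD1) had ratios of 3.82 in H441 and 1.56 in H1437, and its 5 further probe sets measured in H441 gave 1.55, 1.82, 2.21, -0.13 and -0.33, while 7 in H1437 lay between 0.29 and 2.09. In H292, AXL was already at 1627 in the vector array and had a ratio of 0.05, MYLK one of -0.03, and 4 of 26 members were over 2-fold higher and 2 lower, with a median of 0.14 inside the random range. DKK3, a secreted Wnt modulator, was higher in H292 (1.24) and H1437 (4.58), with 0.52 and 2.04 at the lowest of its 3 further probe sets, and stood at -0.08 in H441, where it lay below the array median. The list was higher over the 3 lines by camera with a preset correlation (mean of 23 tested members 1.06, adjusted p 3.72e-11). With an estimated correlation the adjusted p = 0.503, and 0 members passed over all genes or when adjusted over the list alone. The mean was 0.52 without H1437 and 0.60 with the mean of all probe sets of a gene.

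Vimentin (VIM), a mesenchymal intermediate filament gene chosen after its values were seen, went in opposite directions. It read 113.2 and 1212 in H441, a ratio of 3.25, and 27.8 and 447.4 in H1437, a ratio of 3.40, but 203.0 and 13.7 in H292, a ratio of -2.88.

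Among EMT transcription factors, SOX9 was over 2-fold higher in every line at its brighter probe set, the other giving 0.82 in H441. SNAI2, which encodes the Snail relative Slug, had a ratio of 4.09 in H1437 (108.0 to 2093) against 0.43 in H441 and 0.47 in H292, and ZEB1, another repressor of CDH1, had 3.60 in H1437, 0.98 in H441 and -0.50 in H292. SNAI2 in H441 and ZEB1 in H292 lay below the array median, so that neither was measured there. ETS1 had ratios of 0.42, 0.64 and 1.61 in H441, H292 and H1437, with 1.58 and 0.84 at its further probe sets in H1437. The list median was 0.02 in H441 and -0.02 in H292, inside the random range, and 0.93 in H1437, above it. The list holds SNAI1, the gene carried by the virus, at 2.37 in H1437. That median and the camera result below include it and were not recomputed without it, so they are not independent of the construct. FOXQ1 had 1.21 in H292 and was lower in H441 (-0.63) and H1437 (-1.52). TWIST2 read 129.7 and 39.3 in H292, a ratio of -1.40, and lay below the array median in the other lines. TCF4, TCF3, FOXC2, PRRX1, TCF7L2 and TBX3 had ratios between -0.83 (TCF4 in H1437) and 0.79 (FOXC2 in H441, where it lay below the array median). ZEB2, TWIST1, SNAI3, GSC, KLF8 and LEF1 lay below the array median in all 6 arrays. The list was higher by camera with a preset correlation (mean of 11 tested members 0.51, median 0.08, adjusted p 0.0101), with an adjusted p = 0.503 with an estimated correlation, and 1 member, SOX9, passed when adjusted over the list alone. Without H292 the list's adjusted p was 0.0590 (mean 0.63), without H1437 0.0803 (mean 0.23), without the block 0.141 and without the filter on dim genes 0.0653 (mean 0.29).

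Genes of the TGF-beta response list were higher as a group in the Snail-labelled arrays of all 3 lines, with list medians of 0.55 in H441, 0.34 in H292 and 0.62 in H1437, all above the random range. Activity of the pathway itself was not measured. The members with the largest ratios differed by line. ID2 and ID3, inhibitors of basic helix-loop-helix factors, had 2.90 and 2.0 in H441 against 0.57 and 0.64 in H1437, while the ligand gene TGFB2 had 2.88 and the latent TGF-beta binding protein gene LTBP2 2.40 in H1437 against 0.17 and 0.24 in H441. Of 22 tested members, 13 were higher in all 3 lines and 0 lower in all 3. JUNB, also a member, had ratios of -1.17 in H441, 0.00 in H292 and -0.94 in H1437. Camera with a preset correlation gave an adjusted p of 6.82e-09 (mean 0.58), the adjusted p = 0.502 with an estimated correlation, and 0 members passed when adjusted over the list alone.

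Matrix and protease genes were led by COL1A1, COL7A1 and THBS1, with list medians above the random range in H292 (0.21) and H1437 (0.25) and inside it in H441 (0.05, at the 44.6th percentile). COL1A1, a fibrillar collagen gene, had a ratio of 4.40 in H1437, 0.76 in H292 and -0.05 in H441, and its 3 further probe sets measured in H1437 gave 4.24, 2.34 and -0.04. COL7A1, the anchoring fibril collagen, had 2.0 in H1437, 0.95 in H292 and 0.41 in H441, where it lay below the array median, and laminin alpha 5 (LAMA5) was lower in H1437 at -3.51. Integrin genes had medians inside the random range in H441 (0.02) and H292 (0.11) and above it in H1437 (0.32), where ITGB8 had 3.34, ITGA5, a subunit of the fibronectin receptor, 1.70 and ITGB4 1.29. Both lists were higher by camera with a preset correlation (adjusted p 0.00310 for matrix, mean of 30 members 0.27, and 0.0456 for integrins, mean of 16 members 0.25). With an estimated correlation the adjusted p = 0.502 for matrix and the adjusted p = 0.691 for integrins, and 2 matrix genes, THBS1 and COL12A1, and 0 integrin genes passed when adjusted over the list alone. COL12A1, named after its values were seen, had ratios of 1.44, 1.12 and 0.77 in H441, H292 and H1437. Both calls ended without H292 (adjusted p 0.0590 and 0.10), although the means were then 0.30 for both lists, and without the block (0.112 and 0.158), which leaves the means as they are, and the matrix mean was 0.18 without H1437 as well as without the filter on dim genes. The integrin call also ended without H1437 (adjusted p 0.604, mean 0.08) and with the mean of all probe sets (0.173, mean 0.14). It ended as well with a pseudocount of 1 (0.0704, mean 0.30), without the filter (0.0687, mean 0.21) and with the 75th percentile filter (0.117, mean 0.23).

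Inflammatory cytokine genes were higher in all 3 lines by their list medians, 0.42 in H441, 0.54 in H292 and 0.63 in H1437, all above the random range. Interleukin 6 (IL6) had ratios of 0.82, 2.37 and 0.63 in H441, H292 and H1437, and interleukin 11 (IL11) 3.64 in H1437, 1.31 in H292 and -0.18 in H441, where IL11 lay below the array median. LCN2, which encodes the iron-binding protein lipocalin 2, was lower in H441 (-2.21) and H292 (-1.60) and higher in H1437 (1.10). Camera with a preset correlation gave an adjusted p of 6.71e-05 for 17 tested members (mean 0.46), with an adjusted p = 0.502 with an estimated correlation, and 1 member, TNFAIP3, passed when adjusted over the list alone.

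The CXCR2 ligands, chemokines that attract neutrophils, did not move together. In H1437, CXCL1 read 673.9 in the vector array and 56.7 in the Snail-labelled one, a ratio of -3.25, with -2.06 for CXCL2, -1.39 for CXCL3, -2.08 for PPBP and -0.90 for CXCL8. In H292, CXCL2 had 1.3, CXCL8 0.91, CXCL1 0.61 and CXCL3 0.33, while CXCL5 had -1.49. In H441, PPBP had 1.18, CXCL8 0.44 and CXCL3 0.61, while CXCL1 had -0.62 and CXCL2 -0.65. CXCL6 lay below the array median in all 6 arrays. The list medians of 0.44 in H441, 0.61 in H292 and -2.06 in H1437 lay outside the random range, and that of H441 was -0.10 with the 75th percentile filter. With 4 tested members the list was too short for camera, and 0 passed when adjusted over the list alone.

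Interferon response genes were the largest group difference in H292. There 25 of 34 measured members were over 2-fold higher in the Snail-labelled array and 0 lower, with a list median of 2.04, above all 10000 random lists. The 2'-5' oligoadenylate synthetase relative OASL went from 40.0 to 982.4, a ratio of 4.16, MX2, an antiviral GTPase, had 3.86, IFI27 3.84, IRF7, a transcription factor that induces interferon genes, 3.71, IFI6 3.43 and IFIT1 3.27. In H441 the median was 0.14, inside the random range, with 1 of 30 members over 2-fold higher, BST2, which encodes the virus-tethering protein tetherin, at 2.01. In H1437 the median was 0.29, above the random range, with 9 of 30 members over 2-fold higher and 6 lower. IFIT1 stood there at 2.98 and IFI6 at 2.26, OASL at 0.00 and IRF7 at -0.40. The median of the leukocyte markers in H292 was -0.01. Over the 3 lines camera with a preset correlation gave an adjusted p of 8.62e-10 (mean of 31 tested members 0.73), which became 0.0811 (mean 0.20) without H292, with an adjusted p = 0.503 with an estimated correlation and 0 members passing when adjusted over the list alone.

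Lung lineage genes were lower in H1437 and H441. The H1437 median was -1.28, with 12 of 22 measured members over 2-fold lower and 2 higher, among them CEACAM6 at -5.90, AGR2 at -5.49, FOXA2, a transcription factor of endodermal epithelium, at -4.17 (-2.51 at its other measured probe set) and SOX2 at -3.75, although its 2 further measured probe sets gave -0.88 and -0.91. In H441 the median was -0.34, with 3 of 19 over 2-fold lower and 1 higher, SOX2 at 1.05 (0.54 and 0.51 at its further probe sets). In H292 it was 0.15, inside the random range. Stem cell associated genes had medians of -0.97 in H1437 and -0.40 in H292, both outside the random range, and of -0.08 in H441, inside it, but the H292 median was 0.02 with the 75th percentile filter. The aldehyde dehydrogenase gene ALDH3A1 had -3.61 in H1437 and -2.65 in H292, HES1, a Notch target, -3.23 in H1437, and NOTCH3 ratios of -1.18, -0.61 and -1.11 in H441, H292 and H1437. Camera with a preset correlation called both lists lower (adjusted p 0.00505 and 0.00555, means -0.49 and -0.48), with an adjusted p = 0.503 for both with an estimated correlation and 0 members of either passing when adjusted over the list alone. Neither call stood without H1437 (0.151 and 0.166, means -0.10 and -0.12) or with the 75th percentile filter (0.174 and 0.117, the stem cell mean then -0.27). The lung lineage call also ended without H441 (0.294) and with the mean of all probe sets (0.142), with means of -0.61 and -0.41, and its mean was -0.68 with the 75th percentile filter and -0.76 without H292.

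Of the 23 lists tested, 13 passed with the preset correlation, 7 higher and 6 lower, while 0 passed with an estimated correlation (smallest adjusted p = 0.502) and 0 with fry (smallest adjusted p 0.360). The number was 12 without H441, 8 without H292, 7 without H1437 and 9 without the block.

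**Figure D3:**
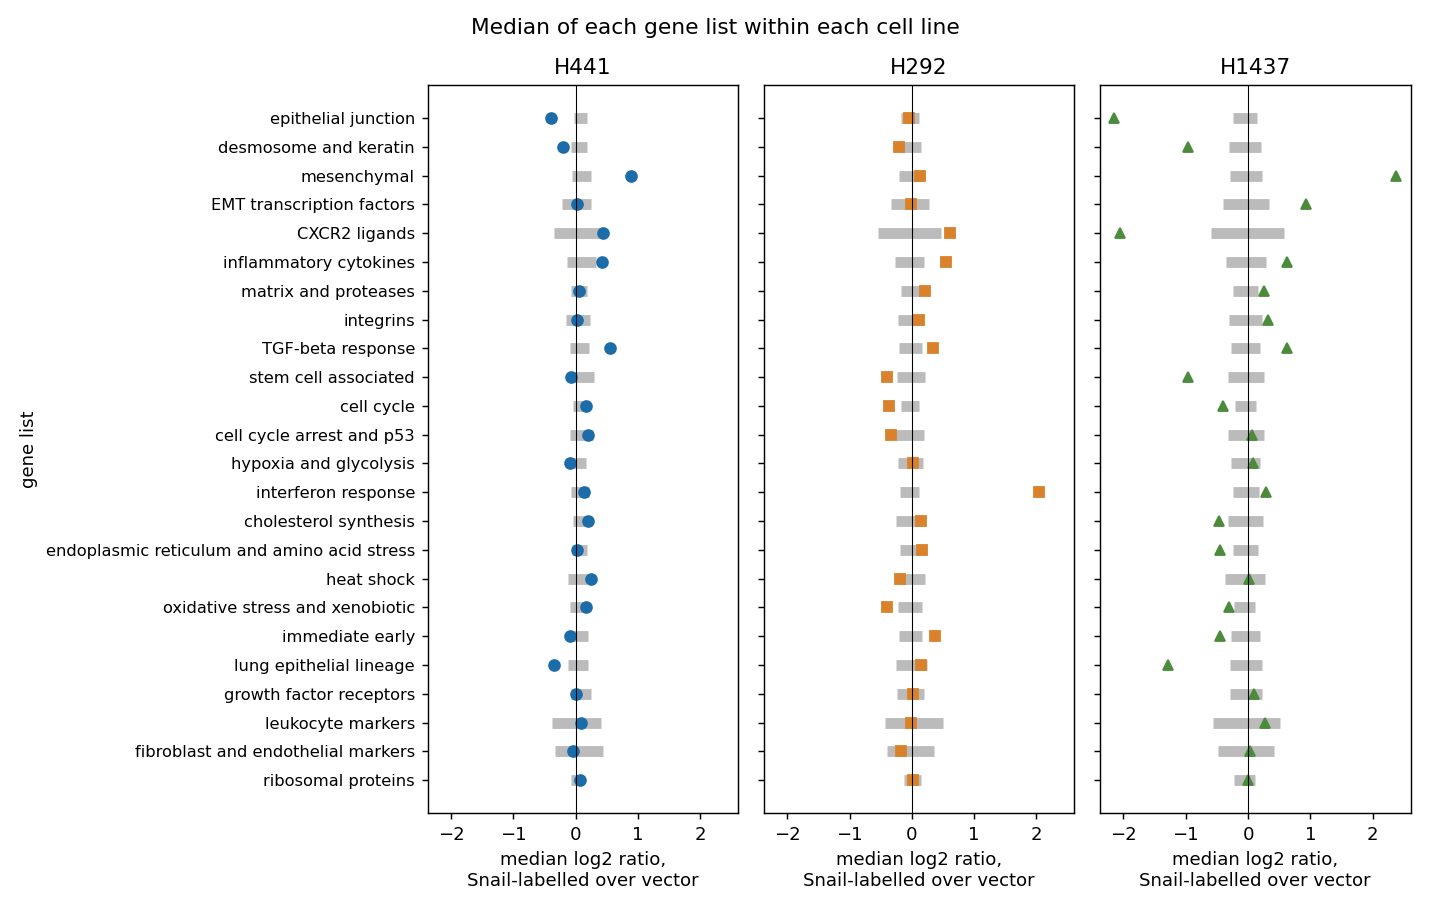
Median log2 ratio of the Snail-labelled over the vector array (horizontal axis) for the members of each fixed gene list measured in a line (vertical axis), with 1 panel per cell line and grey bars over the central range of the medians of random lists matched on expression; the 293-derived marker list, with 3 measured members in H292, is left out. Interferon genes stand at 2.04 in H292, and the junction and mesenchymal lists at -2.15 and 2.38 in H1437.

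Within single lines, the arrays of H441 differed least. There 298 of 12744 measured genes differed by over 2-fold, 207 higher and 91 lower in the Snail-labelled array. SPARC, a collagen-binding matrix glycoprotein gene, went from 7.95 to 610.5, a ratio of 4.71 (2.48 at its other measured probe set), followed by CALD1 (3.82), the fatty acid elongase gene ELOVL5 (3.58, with 0.03 at its other measured probe set), the pentraxin gene PTX3 (3.52) and AXL (3.37). The lowest were the sialyltransferase gene ST6GALNAC1 (-2.26), LCN2 (-2.21), the VEGF receptor gene KDR (-2.13), PLEKHS1 (-2.08) and the phosphate transporter gene SLC34A2 of alveolar type II cells (-2.07). The share of higher genes, 69.5%, was 56.2% after quantile normalization, with 163 higher and 127 lower.

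In H292, 649 of 13062 measured genes differed by over 2-fold, 349 higher and 300 lower. With each array centred on its median the split was 320 higher and 337 lower, and after quantile normalization 365 and 289. Besides the interferon genes OASL, MX2, IFI27 and IRF7, the highest was TCIM, a Wnt pathway regulator, which went from 61.3 to 2416, a ratio of 4.98. The lowest were osteopontin (SPP1), which went from 685.2 to 13.2, a ratio of -4.58, the annexin gene ANXA10 (-3.29), PRR34-AS1 (-3.20), NIBAN1 (-3.14) and the aldo-keto reductase gene AKR1C2 (-3.07).

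H1437 had the most differences, 1767 of 13136 measured genes over 2-fold, 899 higher and 868 lower. SPARC went from 2.17 to 1061, a ratio of 5.89 (2.86 at its other measured probe set), and was followed by the teneurin gene TENM2 (5.86), the calcium-binding protein gene S100A2 (5.53), AXL (5.14) and SCG5 (5.14). The lowest were TC2N (-6.32, with -5.64 and -2.25 at its further probe sets), CEACAM6 (-5.90), ESRP1 (-5.71), AGR2 (-5.49) and the protein kinase A inhibitor gene PKIB (-5.37, with -3.0 at its other measured probe set). These counts have no test, since each rests on 1 array per construct.

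The lines shared a small part of these differences. In all 3 lines, 4 genes were over 2-fold higher at the probe set used (SAMD9, SOX9, TNFAIP3 and TUBA1A), where independent lists would give 0.255, and 2 were over 2-fold lower (AGR2 and TSPAN1), where they would give 0.0784. H441 and H1437 shared 70 higher genes (11.4 if independent) and 20 lower ones (4.18), AXL, CALD1 and PTX3 among the higher, with 23 in opposite directions (15.6). H292 and H1437 shared 66 higher (17.4) and 55 lower (14.6), with 69 in opposite directions (32.0), and H441 and H292 shared 12 higher (4.16) and 4 lower (1.28), with 20 in opposite directions (5.01). Across the 12683 tested genes, which are not independent replicates, Pearson's r of the ratios was -0.17 between H441 and H292 (Spearman's rho -0.22), 0.15 between H441 and H1437 (rho 0.06) and 0.10 between H292 and H1437 (rho 0.10), in a family of 3 comparisons. All 3 ratios had the same sign in 21.5% of genes, against 25% if signs were independent.

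By histology, the effect in H292 set against the mean of H441 and H1437 differed by -4.21 for AXL and -2.74 for MYLK on the log2 scale, each at its brightest probe set, and by 4.31 for OASL and 3.98 for IRF7. Neither these nor any other gene passed in limma, which called 0 of 12683 genes (smallest adjusted p 0.722), with 472 at an unadjusted p under 0.05. With trended and robust moderation 91 genes passed. In simulated data either setting recovered 0 of 200 changed genes, and with 1 mucoepidermoid line the comparison is one of H292 with the other lines.

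The 3 transduced lines differed far more from each other than the arrays within a line did. NKX2-1, the lung lineage transcription factor gene, read 1827 and 1610 in the vector and Snail-labelled arrays of H441 against 4.87 and 7.78 in H292, and CDH11, a mesenchymal cadherin gene, and VSIG1 were also highest in H441. IGFBP7, MFAP5 and OLR1, a receptor gene for oxidised low-density lipoprotein, were highest in H292, where MFAP5 read 1943 and 1984 against 26.1 and 37.8 in H1437. The aldo-keto reductase genes AKR1C2 and AKR1C3 and the carboxylesterase gene CES1 were highest in H1437, where AKR1C3 read 4943 and 5817. IGFBP7 went from 13.5 to 978.5 in H1437 and AKR1C3 from 185.3 to 19.3 in H292, so these markers were not constant within a line. The limma F test called 2204 of 12683 genes between the 3 lines (4586 at an unadjusted p under 0.05), with 106 called without H441, 689 without H292 and 3379 without H1437.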

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

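The tests of array scaling, leukocyte RNA, a shared response, culture differences and the SNAI1 level in this part were chosen after the results they bear on had been seen, and the test of line identity and the counts of other splits before. None of the differences between lines given here was tested, since each line has 1 array per construct.

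Of the genes named in the text, 12 were over 2-fold higher in one line and over 2-fold lower in another. The annexin gene ANXA10 differed by 7.53 on the log2 scale between H1437, where it was higher, and H292, where it was lower. S100A2 differed by 6.78 between the same lines in the same sense, and vimentin (VIM) by 6.29. The immediate early genes FOS and EGR1 were higher in H292 and lower in H1437, by differences of 6.67 and 5.91, as were CXCL2 (3.36) and FOXQ1 (2.73). SOX2 (4.80) and PPBP (3.26) were higher in H441 and lower in H1437, with PPBP a dim probe set that reached 76.8 at most, and SOX2 within 2-fold in both lines at its 2 further measured probe sets (0.54 and 0.51 in H441, -0.88 and -0.91 in H1437). NIBAN1 (4.92) and CES1 (3.86) were higher in H441 and lower in H292, with 0.61 for NIBAN1 in H441 at its other measured probe set, and LCN2 (3.31) was higher in H1437 and lowest in H441.

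List medians lay outside the random range in opposite directions in 4 cases. The CXCR2 ligand median was 0.61 in H292 and -2.06 in H1437, a difference of 2.67 over 5 measured members in each. The immediate early median was 0.38 in H292 and -0.45 in H1437, a difference of 0.825. For endoplasmic reticulum and amino acid stress genes the difference between these lines was 0.609 in the same sense, and the cell cycle medians of H441 and H1437 differed by 0.568.

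Interferon genes were higher in the Snail-labelled H292 array. Array scaling does not account for it, since the list median there was 2.03 after quantile normalization. RNA from leukocytes is argued against by the 5 leukocyte markers measured in H292, of which the largest ratio was 0.42, for CD3E (53.2 to 76.6), while CD14 read 57.7 in the vector and 17.8 in the Snail-labelled array. The arrays came from cultures of established lines, so this test had little to exclude. A response to Snail shared by the 3 lines stays open. The H441 median, 0.14, lay at the 80.3rd percentile of random lists, inside their range and above their middle. That of H1437, 0.29, lay at the 99.8th percentile, above their range. Both were far smaller than the 2.04 of H292. A difference between the H292 cultures unrelated to Snail also stays open, since 1 array per construct cannot be told apart from the culture it came from.

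The lower junction and higher mesenchymal genes were most marked in H1437. Array scaling does not account for this, with a junction median of -2.11 after quantile normalization. Another line in place of H1437 is argued against, because 78.6% (44 of 56) of the genes at least 8-fold brighter in the H1437 vector array than in both other vector arrays were still over 2-fold above those in the Snail-labelled array, against 58 of 58 for H441 and 125 of 127 for H292. A higher SNAI1 level is a candidate explanation, with a ratio of 2.37 in H1437, no rise in H441 and a level below the array median in H292, but 3 lines and 1 probe set of unknown position cannot show whether the level sets the extent.

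The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the adjusted threshold the real split gave 0, a count that all 10 splits reach whatever the data, so this tally says nothing about chance; the highest other was 479. With the line as a block, a split that parts the arrays of 1 line tests the difference between those 2 arrays alone, and the 479 came from the 2 splits that part H1437 alone, while those that part H292 alone or H441 alone gave 0. For genes at an unadjusted p under 0.05 the real count was 501 and the highest other 2089, again from parting H1437 alone (784 among those that part all 3 pairs), with 5 splits as high as the real one. For lists passing camera with the preset correlation the real split gave 13 and the highest other, from parting H1437 alone, 11 (8 among those that part all 3 pairs), so 1 split, the real one, reached that number.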

How the results depend on the processing

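None of the alternatives in this part was chosen after the results had been seen. The count of 0 genes over the 3 lines held under each of them that kept all 3 lines, no block included (0), and it ranged from 0 to 4 when a line was left out. The mean ratio of CDH1 stayed negative, from -1.42 to -0.23 without 1 line, and that of SNAI1 ranged from -0.0842 to 1.27, turning negative without H1437, the line with the large ratio. Lists past camera ranged from 7 to 12 without 1 line, and were 0 with an estimated correlation and 0 with fry; without the block 9 lists passed, the calls of EMT transcription factors, matrix and proteases, integrins and oxidative stress having ended, and leaving out the block changed no other call. Genes differing between lines ranged from 106 to 3379 without 1 line, and were 1397 with the 75th percentile filter, 4367 over every probe set and 3710 at an adjusted p of 0.1. The histology difference gave 91 genes with trended and robust moderation and 0 under the other settings it was run with. It was not run with array weights, the unmoderated paired fit, no block or a line left out.

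Counts over 2-fold depended on the pseudocount and the threshold. With a pseudocount of 1 they were 500 in H441 and 979 in H292, with shared directions in 41 genes for H441 and H292, 158 for H441 and H1437 and 192 for H292 and H1437. With a pseudocount of 64 the counts were 117, 282 and 1122 in H441, H292 and H1437, and 5, 41 and 47 for the pairs in that order. The 75th percentile filter gave 147 and 389 in H441 and H292, and 9, 52 and 65 for the pairs. The mean of probe sets gave 192 and 424, and 80 shared by H292 and H1437. At 1.5-fold the counts were 1353, 2355 and 3787, and 134, 379 and 537 for the pairs, and at 3-fold 72, 159 and 758, and 2, 19 and 19. A lower pseudocount and a lower threshold admit more genes by construction.

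With the 75th percentile filter, 3 list medians outside the random range changed sign, from 0.44 to -0.105 for the CXCR2 ligands and from -0.09 to 0.0167 for hypoxia and glycolysis in H441, and from -0.40 to 0.0245 for stem cell associated genes in H292. With the mean of probe sets, hypoxia and glycolysis in H441 stood at 0.0477. The cause was not tested beyond the smaller number of members left by the filter. Signal over background limits the dim genes, whose ratios shrink under the pseudocount of 16.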

Other observations

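The test of NF-kB target genes in this part was chosen after the values of TNFAIP3 and SOD2 had been seen.

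Xenobiotic and oxidative stress genes were lower in the Snail-labelled arrays of H292 and H1437. In H292 the median was -0.39, with AKR1C2 at -3.07 and AKR1C1, a related aldo-keto reductase, at -2.58. In H1437 the median was -0.30, with AKR1B10 at -3.63 (11716 to 934.8) and glutathione peroxidase 2 (GPX2) at -2.46. Both medians lay outside the random range, and that of H441, 0.17, inside it. Camera with a preset correlation gave an adjusted p of 0.0172, which became 0.263 without H292, 0.0580 without H1437 and 0.141 without the block, with an adjusted p = 0.503 with an estimated correlation, and the mean of -0.29 became -0.53 without H441, -0.17 without H292 and -0.19 without H1437. Cell cycle genes were lower in H292 (median -0.36) and H1437 (-0.40) and higher in H441 (0.17), all outside the random range, with RRM2, a subunit of ribonucleotide reductase, at -0.83, -0.82 and 0.14 and the phosphatase gene CDC25A at -1.15, -0.98 and 0.89, although its 2 further measured probe sets gave -0.61 and 0.16 in H292. Camera gave an adjusted p of 0.00275, the adjusted p = 0.819 with an estimated correlation, 0.199 without H292 and 0.395 without H1437, and the mean of -0.17 became -0.39 without H441, -0.08 without H292 and -0.03 without H1437. Of single genes, 0 members of either list passed when adjusted over the list alone.

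Immediate early genes, which respond within minutes to growth factors and handling, had FOS at 1.65 and EGR1 at 1.89 in H292, -5.02 and -4.02 in H1437 and -1.07 and -1.72 in H441, and the list did not pass over the 3 lines (adjusted p 0.505), but did without H292 (0.00532). In H292 the p53 and arrest list had a median of -0.33, outside the random range. Cholesterol synthesis genes had a median of -0.47 in H1437, outside the range, with DHCR7 at -1.23, and heat shock genes one of 0.25 in H441. The cystine transporter gene SLC7A11 had -2.22 in H292, and PSAT1, of serine synthesis, -2.06 in H1437. The list tests of p53 and arrest (adjusted p 0.827), hypoxia and glycolysis (0.827, with a mean of 0.00 and a camera direction of lower), cholesterol synthesis (0.520), endoplasmic reticulum and amino acid stress (0.520, with a mean of -0.09 and a median of 0.01), heat shock (0.621) and growth factor receptors (0.827) did not pass.

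Among markers of other cells, the leukocyte list (adjusted p 0.520), the fibroblast and endothelial list (0.827, with a mean of 0.11 and a camera direction of lower) and ribosomal proteins (0.827) did not pass. LAPTM5, a lysosomal membrane protein gene of blood cells, went from 9.37 to 156.4 in H1437, a ratio of 2.76 (0.86 at its other measured probe set), and PECAM1, an endothelial marker gene, had ratios between -0.22 and -0.04. Of the markers of 293-derived cells, which made the virus, 1 of 11 on the array was tested, DLK1, with ratios of -0.49, 0.47 and -0.37.

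SOD2, a mitochondrial superoxide dismutase gene chosen after its values were seen, had ratios of 0.80 in H441, 1.35 in H292 and 1.04 in H1437. Since SOD2 and TNFAIP3 are both induced by NF-kB, a list of 29 other NF-kB target genes was drawn up, 14 of them also in another list and 10 of these in the cytokine or CXCR2 ligand lists. Its medians are therefore not independent of those given above for these 2 lists. The hypothesis was that these targets may be higher in all 3 lines. The list median was 0.32 in H441 and 0.63 in H292, at the 99.8th percentile and above all random lists, and 0.16 in H1437 at the 96.2nd percentile, where 4 members were over 2-fold higher and 4 lower. The lowest percentile of the 3 lines, 96.16, lies inside the random range but above its middle, so the hypothesis stays open.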
